A study of Mus musculus with 18 samples.

How the data were processed

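Gene expression was measured on 18 Affymetrix whole-genome mouse arrays, with RNA from mouse embryonic fibroblasts of 3 genotypes (WT, Atf4-/- and Cebpg-/-) kept for 3 h in normal medium or in amino acid-deprived (AAD) medium. Each of the 6 groups had 3 arrays. The deposited values are log2 probe set values, and per the submitters' processing notes they were made with RMA, whose version is not given. The range of the values (2.15 to 14.56) and the array medians (5.21 to 5.27) were checked against that unit, and the values were used without further normalization. The spread of single probes behind each value is not given in the sources used here, so the precision of each comparison rests on the 3 arrays per group alone.

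Each array held 45101 probe sets. The probe annotation listed 35890 of them, 34958 with 1 gene symbol and 932 with several, and 9211 were not listed. Probe sets with several symbols or no listing were left out. Of those with 1 symbol, 34754 were matched by Entrez identifier in a GRCm38.p6 gene table, which was used for names and for the distance between genes only. Where a gene had several probe sets, the one with the highest mean over all 18 arrays was used, which gave 18194 genes. Genes whose highest group mean lay under the 40th percentile of all values (4.65) were left out, and 13728 genes were tested.

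The comparisons were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 6 groups, 12 residual degrees of freedom, moderated variances and Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. The 10 comparisons were AAD against normal medium in each genotype, the difference of that response between each knockout and WT and between the knockouts, and each knockout against WT in each medium. A response is the log2 change under AAD, so that a fall that was less deep counts as a higher response. AAD-induced genes were those called in WT with a rise of at least 2-fold (log2 change of 1). The plan gave the median response of these genes as a description. A comparison between genotypes over pairs of arrays was added later, with an exact 2-sided permutation test, whose smallest possible p with 3 pairs against 3 is 0.1. All errors of log2 changes are standard errors from limma with n = 3 arrays per group, and all errors of levels are standard deviations.

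The 29 gene lists, the rule for named genes, the comparisons and the alternatives listed first below were fixed before the data were examined. Each list was tested against all other genes with camera from limma at a preset correlation of 0.01, with adjustment over all 290 tests, and 100 tests were called. Counts of members are of those tested. With a correlation estimated from the arrays instead, 20 of them were called. The test fry, which sets a list against no change and not against other genes, was run as a further alternative. Genes near the targeted loci (20 Mb) were compared with other genes by Fisher's exact test.

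The rule for named genes took Atf4 and Cebpg, the 10 largest rises and falls of at least 2-fold among called genes for AAD in WT and for each difference of a response from WT, and the 5 largest for each other comparison. For comparisons of 2 groups it also required that all 3 arrays of a group lay above all 3 of the other. It took the 4 members with the largest change in each list described, members of the lists of stress response regulators, C/EBP and ATF factors and glutathione synthesis, and any gene in a count of 5 or fewer. Genes without a proper name were counted and skipped, and the text names part of the genes taken. Any other gene named is said to have been chosen after its values were seen.

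Whether the replicate numbers pair the arrays was tested on residuals from the group means. The arrays of the same genotype and number in the 2 media correlated at 0.30 to 0.69 in 9 of 9 pairs, those of the same genotype and another number at -0.56 to 0.09, and those of other genotypes with the same number and medium at -0.24 to 0.19. A replicate block within genotype was therefore added as an alternative after seeing the data, for the responses to AAD and their differences: with the replicate block, 5380 genes changed under AAD in WT, against 3865 without it.

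The WT arrays serve both knockouts, so overlaps are given beside those of independent lists and 50 simulations with shared WT arrays but no effects. Without effects almost no gene is called, so low simulated overlaps are built in and show no excess. Splitting the WT arrays was not possible with 3 per group, so part of any excess may come from the shared arrays. The fit was tested on simulated data with 50 changed genes per fold. For AAD in WT it recovered 88% of simulated 1.5-fold changes and 100% of 2-fold, 3-fold and 4-fold changes. For the difference between the responses of Atf4-/- and WT it recovered 64%, 88%, 98% and 100%, and each fit called 7 of 13528 genes without a simulated change.

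Alternatives set at the start were no filter or a filter at the 60th percentile, the mean of a gene's probe sets, probe sets with the suffixes _x_at and _s_at left out, a trended and robust variance prior, array weights, the groups of a comparison alone, each array shifted to the same median, a further quantile normalization, a replicate number common to all groups, a 2-fold minimum added or dropped, a class defined by the level in AAD medium, other distances from the loci, and each array left out in turn. Further ones were chosen after seeing the data: the replicate block within genotype as a fixed or random term and with an estimated correlation in the list tests, both arrays of a replicate number left out, genes on chromosomes X and Y left out, and macrophage-type genes left out.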

Results

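The data came from mouse embryonic fibroblasts, connective tissue cells grown from embryos, on 18 arrays. The cells were wild type (WT) or lacked Atf4 or Cebpg, and stood for 3 h in normal medium or in amino acid-deprived (AAD) medium, a Krebs-Ringer buffer with supplements. ATF4 is a transcription factor that is made when phosphorylation of the initiation factor eIF2 slows other translation, the integrated stress response. C/EBPγ, encoded by Cebpg, is a bZIP protein that can pair with it. Each of the 6 groups had 3 arrays, which limits the precision of every value. Of 13728 genes tested, the median residual standard deviation was 0.109. Changes are log2 differences ± SE with n = 3. The labels do not say whether replicates came from separate embryos, so p-values measure only the spread between these samples.

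The targeted genes came first. In normal medium the brightest Atf4 probe set stood at 12.10 ± 0.07 (SD, n = 3) in WT cells, 6.50 ± 0.16 in Atf4-/- cells and 12.31 ± 0.03 in Cebpg-/- cells, and the difference between Atf4-/- and WT was -5.59 ± 0.09 (adjusted p = 1.53e-15). A second Atf4 probe set stood at 10.72 ± 0.21 in WT and 3.64 ± 0.16 in Atf4-/-, while the last Atf4 probe set had group means between 4.52 and 5.01, near the level of 4.65 below which genes were not tested. AAD raised Atf4 by 0.75 ± 0.09 in WT and by 0.38 ± 0.09 in Cebpg-/-. Cebpg, read from its brightest probe set, rose by 1.06 ± 0.11 in WT. In Atf4-/- cells Cebpg was lower than in WT in normal medium (-1.36 ± 0.11) and its change under AAD was 0.00 ± 0.11 (adjusted p = 0.997), a response lower than in WT (-1.06 ± 0.15, adjusted p = 0.000264). In Cebpg-/- cells the same probe set was not reduced in normal medium (0.05 ± 0.11, adjusted p = 0.805), and in AAD medium it was lower than in WT (-0.74 ± 0.11, adjusted p = 0.000133). Its response differed from that of WT by -0.79 ± 0.15 (adjusted p = 0.0507, or 0.0032 with the replicate block). The 2 other Cebpg probe sets stood at 8.25 ± 0.10 and 5.38 ± 0.21 in WT and at 7.75 ± 0.03 and 5.87 ± 0.13 in Cebpg-/- in normal medium. Whether these probe sets lie in the deleted part of Cebpg was not known, so they gave no check of that deletion.

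**Figure D1:**
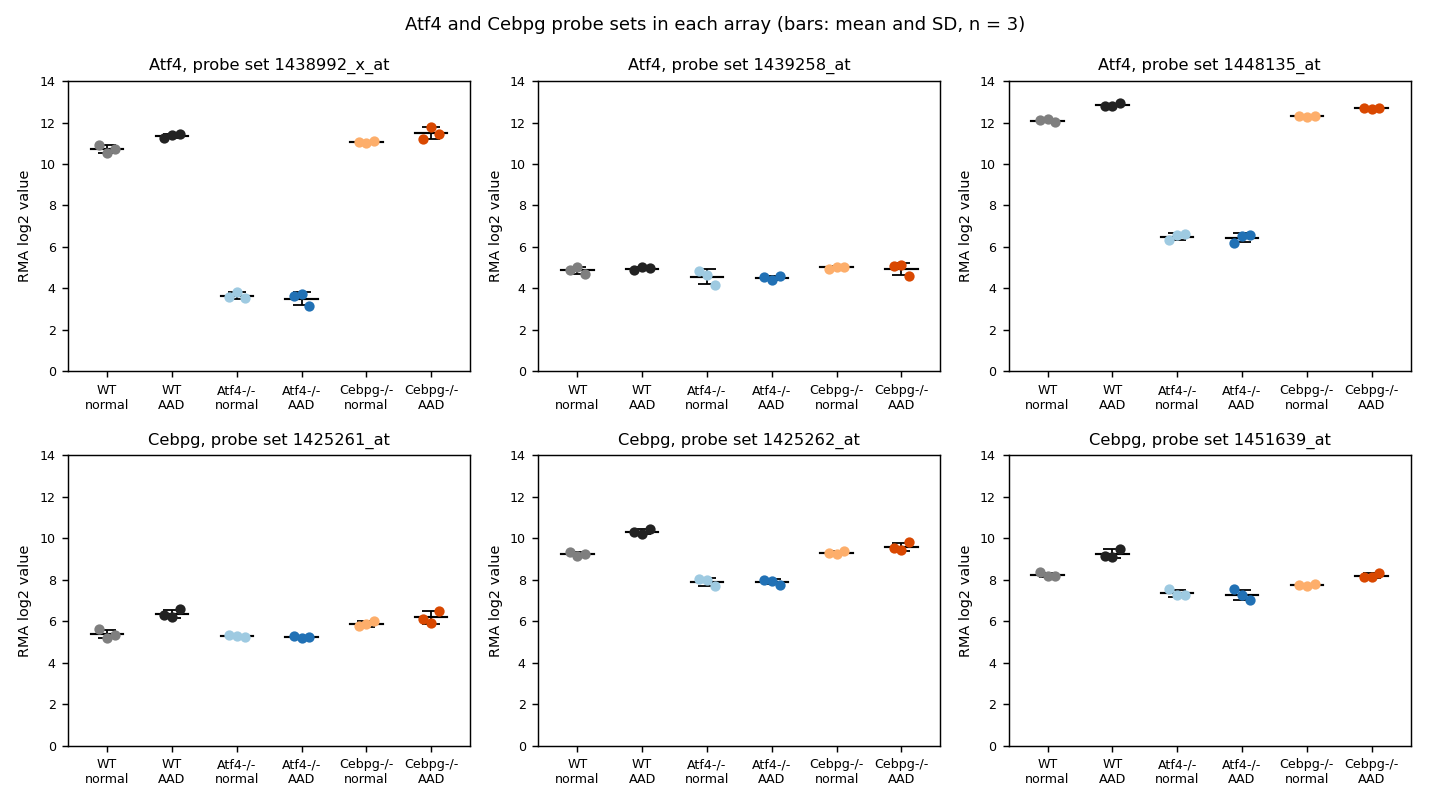
RMA log2 values of the Atf4 and Cebpg probe sets on each of the 18 arrays (points), with the mean and SD of 3 arrays (bars). The Atf4 probe sets with a clear signal were far lower in Atf4-/- cells (6.50 against 12.10 and 3.64 against 10.72 in normal medium), while the brightest Cebpg probe set stood at 9.31 in Cebpg-/- and 9.27 in WT in normal medium.

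The first comparison asked which genes WT fibroblasts change in AAD medium. Atf3, a stress-induced transcription factor, rose by 3.67 ± 0.12 (12.73-fold, adjusted p = 9.33e-12), more than any other gene with a proper name. Ppp1r15a, an eIF2 phosphatase subunit gene, rose by 2.75 ± 0.08, and Klhl24 and Crebrf rose by 3.05 ± 0.18 and 2.78 ± 0.15. Ddit3 (CHOP) rose by 2.59 ± 0.10 and Trib3 by 2.16 ± 0.18. Of the integrated stress response regulators, 18 of 22 members rose, 1 fell and 3 did not pass. The stress response median was 1.01 (camera adjusted p = 7e-15, adjusted p = 0.0337 with an estimated correlation), and 19 rose and 1 fell adjusted over the list alone. The C/EBP and ATF family overlaps them (Atf3, Atf5, Cebpb, Ddit3, Jdp2 and the targeted Atf4 and Cebpg) and is not independent. Of its 23 members 15 rose, 1 fell and 7 did not pass, with Nfil3 (1.58 ± 0.09) and Cebpb (1.11 ± 0.09) up. The C/EBP and ATF median was 0.54 (camera adjusted p = 1.87e-08, adjusted p = 0.0337 with an estimated correlation), and 16 rose and 1 fell adjusted over the list alone. The calls of both lists were lost with the replicate block and an estimated correlation together (adjusted p = 0.112 and 0.104).

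Genes of nutrient and growth factor withdrawal rose in WT as well. Of the FOXO-type genes, which rise when insulin-like signalling falls, 15 of 20 members rose and 5 did not pass. The FOXO-type median was 0.86 (camera adjusted p = 6.29e-11, adjusted p = 0.0583 with an estimated correlation), and 15 rose adjusted over the list alone. Their largest rises were in Gadd45a (3.04 ± 0.12), a growth arrest gene, Pdk4 (2.63 ± 0.31), which encodes a kinase that inhibits pyruvate dehydrogenase, Irs2 (2.18 ± 0.11), an insulin receptor substrate, and Trp53inp1 (1.92 ± 0.20). In the autophagy and lysosome list 16 of 31 members rose, 1 fell and 14 did not pass, led by Fnip1 (2.26 ± 0.12) and Flcn (1.67 ± 0.10), the folliculin complex, and by Rragd (1.22 ± 0.22), a Rag GTPase of the mTORC1 pathway. The autophagy and lysosome median was 0.21 (camera adjusted p = 8.14e-06, adjusted p = 0.291 with an estimated correlation), and 17 rose and 1 fell adjusted over the list alone. The FOXO-type call, lost with an estimated correlation alone, was kept with the replicate block and an estimated correlation together (adjusted p = 0.0265 in WT, 0.0255 in Atf4-/- and 0.0255 in Cebpg-/-). Amino acid transporters rose in part: 11 of 22 members rose, 1 fell and 10 did not pass, with the cystine carrier Slc7a11 (1.19 ± 0.13) and the neutral amino acid carrier Slc38a2 (1.17 ± 0.08) at the top. The transporter median was 0.19 (camera adjusted p = 0.0049, adjusted p = 0.158 with an estimated correlation), and 11 rose and 1 fell adjusted over the list alone. Of the aminoacyl-tRNA synthetases, 10 of 19 members rose, 1 fell and 8 did not pass, with Aars up by 0.44 ± 0.06. The synthetase median was 0.25 (camera adjusted p = 0.00255, adjusted p = 0.26 with an estimated correlation), and 10 rose and 2 fell adjusted over the list alone.

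Immediate early and inflammatory genes also rose in WT. Egr1 rose by 2.47 ± 0.17, Fos by 2.43 ± 0.17, Dusp1 by 1.87 ± 0.12 and Myc by 1.78 ± 0.10, and of the immediate early and serum response list 20 of 34 members rose, 6 fell and 8 did not pass. The immediate early median was 0.80 (camera adjusted p = 2.32e-08, adjusted p = 0.156 with an estimated correlation), and 20 rose and 7 fell adjusted over the list alone. The chemokine gene Cxcl2 rose by 3.44 ± 0.19, Ccl2 by 1.57 ± 0.21 and the cytokine gene Il6 by 1.42 ± 0.32. Cxcl2 lay under 4.65 in WT in normal medium (4.28 ± 0.26, SD, n = 3), so the size of its rise is uncertain. Of the inflammatory mediators, 14 of 22 members rose and 8 did not pass. The inflammatory median was 0.66 (camera adjusted p = 3.95e-06, adjusted p = 0.115 with an estimated correlation), and 14 rose and 1 fell adjusted over the list alone. In the list of p53 targets 11 of 21 members rose, 4 fell and 6 did not pass, and Bbc3 (1.47 ± 0.12), Eda2r (1.16 ± 0.10) and Btg2 (1.08 ± 0.14) were among the members that rose. The p53 target median was 0.39 (camera adjusted p = 0.00539, adjusted p = 0.614 with an estimated correlation), and 11 rose and 4 fell adjusted over the list alone. The genes Rgs1 (3.63 ± 0.21), a regulator of G protein signalling, Pnrc1 (2.71 ± 0.11) and Klf11 (2.61 ± 0.10) completed the 10 largest rises.

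Fewer genes fell than rose by 2-fold in WT. The largest falls included Sema7a, a semaphorin (-2.07 ± 0.18), Inka1 (-2.05 ± 0.16), the heat shock protein gene Hspa1b (-1.72 ± 0.22) and Rnf145 (-1.69 ± 0.12). In the sterol synthesis list 10 of 20 members fell and 10 did not pass, including Sc5d (-0.59 ± 0.09) and Idi1 (-0.40 ± 0.09). The sterol median was -0.22 (camera adjusted p = 0.00749, adjusted p = 0.608 with an estimated correlation), and 10 fell and 1 rose adjusted over the list alone. Of the macrophage markers, 6 of 15 members fell and 9 did not pass, with Lyz2 at -1.25 ± 0.18. The macrophage median was -0.35 (camera adjusted p = 0.00515, adjusted p = 0.694 with an estimated correlation), and 8 fell and 1 rose adjusted over the list alone. The smooth muscle markers were not called (camera adjusted p = 0.165) but were lower with the replicate block (adjusted p = 0.0257, or 0.251 with an estimated correlation as well). Over all genes, 1960 rose and 1905 fell (28.2% of those tested), 248 by at least 2-fold upward and 68 downward.

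The second comparison asked what remains of this response without ATF4. In Atf4-/- cells Rgs1 rose by 3.21 ± 0.21, the dendritic cell gene Cd83 by 2.79 ± 0.18, Cxcl2, again from a level under 4.65, by 2.32 ± 0.19 and Pdk4 by 1.52 ± 0.31. Of the FOXO-type genes, 9 of 20 members rose, 1 fell and 10 did not pass, with Irs2 at 1.40 ± 0.11, Fbxo32, a muscle atrophy ubiquitin ligase gene, at 1.29 ± 0.21 and Pik3ip1 at 1.27 ± 0.13. Adjusted over the FOXO-type list alone 13 rose and 1 fell, at a median of 0.34 (camera adjusted p = 3.35e-11, adjusted p = 0.0572 with an estimated correlation). In the autophagy and lysosome list 7 of 31 members rose and 24 did not pass, with Rragd (1.00 ± 0.22) at the top. Adjusted over the autophagy and lysosome list alone 13 rose and 1 fell, at a median of 0.16 (camera adjusted p = 4.57e-06, adjusted p = 0.28 with an estimated correlation). Integrated stress response regulators rose in part: 9 of 22 members rose and 13 did not pass, with Klhl24 (1.10 ± 0.18), Ddit3 (0.85 ± 0.10) and Cebpb (0.82 ± 0.09) at the top. Adjusted over the stress response list alone 12 rose and 1 fell, at a median of 0.29 (camera adjusted p = 1.33e-07, adjusted p = 0.0572 with an estimated correlation). Of the immediate early genes, 12 of 34 members fell, 1 rose and 21 did not pass. Adjusted over the immediate early list alone 14 fell and 3 rose, at a median of -0.16 (camera adjusted p = 1.08e-06, adjusted p = 0.241 with an estimated correlation). Of the ribosome biogenesis genes 4 of 29 fell and 25 did not pass. The ribosome biogenesis median was -0.16 (camera adjusted p = 6.81e-07, adjusted p = 0.551 with an estimated correlation), and 7 fell adjusted over the list alone. In the hypoxia and glycolysis list 2 of 20 members rose and 18 did not pass. The hypoxia and glycolysis median was 0.10 (camera adjusted p = 0.00889, adjusted p = 0.473 with an estimated correlation), and 5 rose and 2 fell adjusted over the list alone.

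Macrophage markers fell in Atf4-/- cells too: 3 of 15 members fell and 12 did not pass, with Lyz2 at -0.95 ± 0.18. Adjusted over the macrophage list alone 4 fell, at a median of -0.22 (camera adjusted p = 0.00683, adjusted p = 0.694 with an estimated correlation). In the C/EBP and ATF family 4 of 23 members rose, 1 fell and 18 did not pass, a call not kept with the replicate block (adjusted p = 0.0531). Adjusted over the C/EBP and ATF list alone 5 rose and 1 fell, at a median of 0.02 (camera adjusted p = 0.031, adjusted p = 0.291 with an estimated correlation). The p53 targets were not called (adjusted p = 0.0627) but were higher with the replicate block (adjusted p = 0.0259), and neither list was called with the block and an estimated correlation together (adjusted p = 0.343 for each). Over all genes, 645 changed, 366 upward and 279 downward, 25 and 7 of them by at least 2-fold. The count was 1523 with the replicate block and 329 with the groups of this comparison alone, and it was 334 without Atf4-/- replicate 1 in normal medium, 339 without replicate 2 in normal medium, 391 without replicate 2 in AAD medium and 351 without replicate 3 in AAD medium. Pdk4 lost its call without Atf4-/- replicate 2 in normal medium (1.32) or replicate 3 in AAD medium (1.34).

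The response itself differed between Atf4-/- and WT. That of Atf3 was lower (-3.08 ± 0.17, adjusted p = 2.39e-08), since Atf3 rose by 0.59 ± 0.12 in Atf4-/-. The responses of Fos (-2.38 ± 0.24), Ppp1r15a (-2.41 ± 0.12), Csrnp1 (-2.29 ± 0.15), Trib3 (-2.04 ± 0.26) and Edn1, which encodes endothelin (-2.19 ± 0.27), were also lower. Of the immediate early and serum response list, 24 of 34 members had a lower response, 1 had a higher response and 9 did not pass, with Myc at -1.89 ± 0.14. For the immediate early list the median was -0.93 (camera adjusted p = 3.93e-22, 0.0337 with an estimated correlation). Adjusted over the list alone 26 had a lower response and 1 had a higher response. Of the integrated stress response regulators, 12 of 22 members had a lower response, 1 had a higher response and 9 did not pass, with Fgf21, a starvation hormone gene, at -2.01 ± 0.29. The 12 include the deleted Atf4 itself (-0.80 ± 0.13), which also counts in the C/EBP and ATF family below. For the stress response list the median was -0.83 (camera adjusted p = 8.98e-13, 0.0337 with an estimated correlation). Adjusted over the list alone 15 had a lower response and 1 had a higher response. In the C/EBP and ATF family 9 of 23 members had a lower response and 14 did not pass, with Nfil3 at -1.90 ± 0.12 and Ddit3 at -1.74 ± 0.14. For the C/EBP and ATF list the median was -0.31 (camera adjusted p = 6.61e-08, adjusted p = 0.0337 with an estimated correlation), and 11 had a lower response adjusted over the list alone. The responses of Sema7a (2.00 ± 0.25), Inka1 (2.04 ± 0.23) and Rnf145 (1.67 ± 0.17), which fell in WT, were higher.

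Further groups differed in their response. Of the inflammatory mediators, 11 of 22 members had a lower response and 11 did not pass, with Tnfaip3 at -1.65 ± 0.17. Adjusted over the inflammatory list alone 11 had a lower response, at a median of -0.69 (camera adjusted p = 4.06e-07, adjusted p = 0.0847 with an estimated correlation). In the FOXO-type list 9 of 20 members had a lower response, 1 had a higher response and 10 did not pass. For the FOXO-type list the median was -0.51 (camera adjusted p = 7.49e-05, adjusted p = 0.28 with an estimated correlation), and 11 had a lower response and 1 had a higher response adjusted over the list alone. The synthetases gave a similar picture: 7 of 19 members had a lower response and 12 did not pass, with Cars (-0.42 ± 0.10) at the top. Adjusted over the synthetase list alone 8 had a lower response and 1 had a higher response, at a median of -0.16 (camera adjusted p = 0.00103, adjusted p = 0.219 with an estimated correlation). Among the amino acid transporters 6 of 22 members had a lower response and 16 did not pass, with Slc7a11 at -1.25 ± 0.18 and Slc38a2 at -1.15 ± 0.11. Adjusted over the transporter list alone 7 had a lower response, at a median of -0.11 (camera adjusted p = 0.00278, adjusted p = 0.134 with an estimated correlation). In Atf4-/- cells Slc7a11 (4.48 ± 0.05 in normal and 4.42 ± 0.07 in AAD medium, SD, n = 3) and Fgf21 (4.60 ± 0.10 and 4.41 ± 0.20) lay under 4.65 in both media, so the sizes of their differences from WT are uncertain. In the autophagy and lysosome list 7 of 31 members had a lower response, 1 had a higher response and 23 did not pass. For the autophagy and lysosome list the median was -0.09 (camera adjusted p = 0.00586, adjusted p = 0.614 with an estimated correlation), and 9 had a lower response and 2 had a higher response adjusted over the list alone. Of the p53 targets 8 of 21 members had a lower response, 2 had a higher response and 11 did not pass. Adjusted over the p53 target list alone 11 had a lower response and 3 had a higher response, at a median of -0.29 (camera adjusted p = 0.0435, adjusted p = 0.776 with an estimated correlation). In the sterol synthesis list 6 of 20 members had a higher response and 14 did not pass. Adjusted over the sterol list alone 6 had a higher response, at a median of 0.25 (camera adjusted p = 0.000172, adjusted p = 0.381 with an estimated correlation). The macrophage markers were not called (adjusted p = 0.23) and had a higher response with the replicate block (adjusted p = 0.0235, or 0.521 with an estimated correlation as well). Over all genes, 1752 responses differed, 966 lower and 786 higher, 174 and 38 of them by at least 2-fold, and 3270 differed with the replicate block, 1746 of them shared. Array weights gave 2857, and the calls of the stress response list (adjusted p = 0.112) and the C/EBP and ATF list (adjusted p = 0.104) were lost with the replicate block and an estimated correlation together, while that of the immediate early list was kept (adjusted p = 0.0255).

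The 248 genes that AAD raised at least 2-fold in WT gave a summary of the loss. Their median rise was 1.35 in WT, 0.29 in Atf4-/- and 1.16 in Cebpg-/-. Over the 3 pairs of arrays of each genotype the medians averaged 1.37 ± 0.03 (SD, n = 3), 0.31 ± 0.03 and 1.17 ± 0.07, and the differences from WT were -1.06 for Atf4-/- and -0.20 for Cebpg-/- (exact permutation p = 0.1 for each, a test added after the plan, the smallest that 3 pairs against 3 allow). Since the genes were chosen on WT arrays, the WT median was also taken with each pair of arrays left out of the choice, and was 1.34. In Atf4-/- cells 215 of the 248 (86.7%) had a smaller response, 104 still rose, and in Cebpg-/- cells 239 rose. Of the 215 genes, 133 were higher than WT in Atf4-/- in normal medium, 31 lower and 51 not different. In AAD medium 157 of them were lower than WT, 22 higher and 36 not different. The pairs of arrays make the replicate block for these classes, which gave 235 genes with a smaller response in Atf4-/-.

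**Figure D2:**
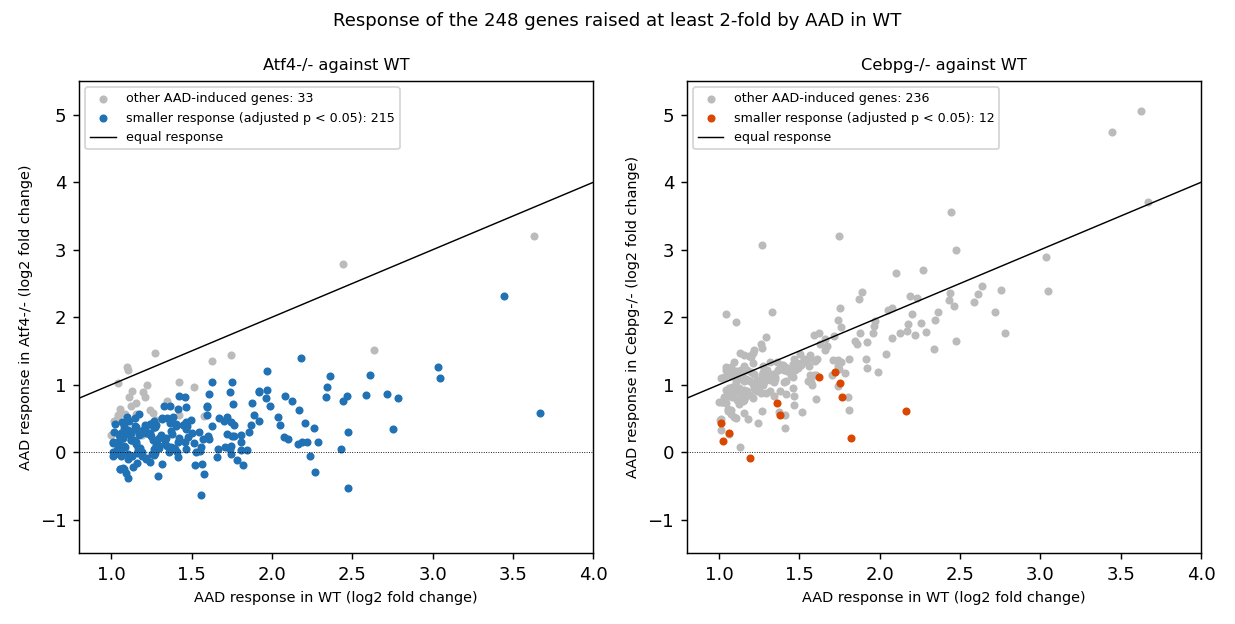
Log2 fold change under AAD of the 248 genes raised at least 2-fold in WT (points), in each knockout (vertical axis) against WT (horizontal axis), with the line of equal response. The response was smaller for 215 genes in Atf4-/- and for 12 in Cebpg-/- (coloured points).

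The next comparison asked what remains of the response without C/EBPγ. In Cebpg-/- cells Rgs1 rose by 5.06 ± 0.21, Cxcl2, from a level under 4.65, by 4.74 ± 0.19, Atf3 by 3.70 ± 0.12, Cd83 by 3.56 ± 0.18 and the chemokine gene Ccl3 by 3.21 ± 0.16. Of the integrated stress response regulators, 12 of 22 members rose and 10 did not pass, with Ppp1r15a at 2.41 ± 0.08 and Ddit3 at 2.23 ± 0.10. The stress response median was 0.62 (camera adjusted p = 6.26e-11, adjusted p = 0.0337 with an estimated correlation), and 14 rose adjusted over the list alone. In the C/EBP and ATF family 12 of 23 members rose, 1 fell and 10 did not pass. The C/EBP and ATF median was 0.28 (camera adjusted p = 6.85e-07, adjusted p = 0.0337 with an estimated correlation), and 14 rose and 1 fell adjusted over the list alone. With the replicate block and an estimated correlation together, the calls of the stress response list (adjusted p = 0.138) and the C/EBP and ATF list (adjusted p = 0.104) were lost, and that of the FOXO-type list was kept. Of the FOXO-type genes 14 of 20 members rose and 6 did not pass. The FOXO-type median was 0.84 (camera adjusted p = 2.54e-12, adjusted p = 0.0544 with an estimated correlation), and 14 rose adjusted over the list alone. Of the immediate early genes 19 of 34 members rose, 2 fell and 13 did not pass, with Egr1 at 2.99 ± 0.17 and Dusp1 at 2.28 ± 0.12. The immediate early median was 0.62 (camera adjusted p = 5.01e-10, adjusted p = 0.11 with an estimated correlation), and 19 rose and 5 fell adjusted over the list alone. In the inflammatory list 13 of 22 members rose and 9 did not pass. For the inflammatory list the median was 0.57 (camera adjusted p = 5.93e-07, adjusted p = 0.0884 with an estimated correlation), and 13 rose adjusted over the list alone. Of the autophagy and lysosome genes 13 of 31 members rose, 2 fell and 16 did not pass. The autophagy and lysosome median was 0.19 (camera adjusted p = 4.15e-06, adjusted p = 0.28 with an estimated correlation), and 16 rose and 4 fell adjusted over the list alone. Among p53 targets 9 of 21 members rose, 1 fell and 11 did not pass. For the p53 target list the median was 0.31 (camera adjusted p = 0.00274, adjusted p = 0.576 with an estimated correlation), and 10 rose and 2 fell adjusted over the list alone. The largest falls included Rab26os (-1.90 ± 0.22) and the leukocyte antigen gene Cd52 (-1.56 ± 0.25). In the sterol synthesis list 7 of 20 members fell, 1 rose and 12 did not pass. For the sterol list the median was -0.20 (camera adjusted p = 0.0225, adjusted p = 0.694 with an estimated correlation), and 9 fell and 1 rose adjusted over the list alone. Of the macrophage markers, 8 of 15 members fell and 7 did not pass, with Lyz2 at -1.23 ± 0.18. For the macrophage list the median was -0.46 (camera adjusted p = 0.000597, adjusted p = 0.576 with an estimated correlation), and 9 fell adjusted over the list alone. Over all genes, 1600 rose and 1413 fell, 194 and 25 by at least 2-fold, and 4663 changed with the replicate block, with which the smooth muscle markers were also lower (adjusted p = 0.0123, against 0.105, or 0.213 with the block and an estimated correlation).

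Few responses differed between Cebpg-/- and WT at the level of single genes. The response of Slc7a11, the cystine carrier, was lower (-1.27 ± 0.18, adjusted p = 0.01), since its change in Cebpg-/- was -0.08 ± 0.13 (adjusted p = 0.712) against 1.19 ± 0.13 in WT. Fgf21 (-1.61 ± 0.29), Trib3 (-1.55 ± 0.26) and the nuclear receptor gene Nr4a1 (-1.03 ± 0.16) were the other genes with a response at least 2-fold lower. The lectin gene Clec4e (1.80 ± 0.30) and Ccl3 (1.47 ± 0.23) had higher responses, as did Akr1c14, of the aldo-keto reductases (1.16 ± 0.20), the cytokine receptor gene Il7r (1.03 ± 0.18), and Sema7a (1.38 ± 0.25), Inka1 (1.19 ± 0.23) and Hivep3 (1.05 ± 0.16), which fell in WT. In WT in normal medium Clec4e (3.80 ± 0.37, SD, n = 3), Ccl3 (4.39 ± 0.07), Akr1c14 (3.71 ± 0.14) and Il7r (4.18 ± 0.15) lay under 4.65, so the sizes of their differences are uncertain. Stress response regulators shifted as a group: 4 of 22 members had a lower response and 18 did not pass, with Jdp2 (-0.66 ± 0.13) and Herpud1 (-0.51 ± 0.10) also called. Adjusted over the stress response list alone 11 had a lower response, at a median of -0.35 (camera adjusted p = 1.48e-10, adjusted p = 0.0337 with an estimated correlation). Of the amino acid transporters, 1 of 22 members had a lower response and 21 did not pass. For the transporter list the median was -0.14 (camera adjusted p = 1.24e-05, adjusted p = 0.0431 with an estimated correlation), and 6 had a lower response adjusted over the list alone. The calls of both lists were lost with the replicate block and an estimated correlation together (adjusted p = 0.137 for the stress response and 0.293 for the transporters). Of 23 C/EBP and ATF members, 1 (Jdp2 again) had a lower response and 22 did not pass. Adjusted over the C/EBP and ATF list alone 3 had a lower response, at a median of -0.17 (camera adjusted p = 5.98e-05, adjusted p = 0.0572 with an estimated correlation). The synthetases (median -0.11, camera adjusted p = 0.00556), the amino acid synthesis genes (median -0.09, adjusted p = 0.0486) and the hypoxia and glycolysis genes (median -0.08, adjusted p = 0.0462) were lower as lists, but not with an estimated correlation (adjusted p = 0.286, 0.55 and 0.614), and with no filter on dim probe sets the last 2 were not called (adjusted p = 0.0695 and 0.0634). In limma 0 of their members passed, and 3 of each list had an unadjusted p under 0.05, all lower. Over all genes 31 responses differed, 20 lower and 11 higher, 4 and 7 of them by at least 2-fold, and 953 had an unadjusted p under 0.05. With the replicate block 189 differed, 99 lower and 90 higher, including all 31.

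With 1 array left out, which leaves 2 in a group, the count was 19, 10 and 9 without WT replicates 1, 2 and 3 in normal medium, 9 without WT replicate 3 in AAD medium, 8, 13 and 16 without Cebpg-/- replicates 1, 2 and 3 in normal medium, and 9 and 51 without Cebpg-/- replicates 2 and 3 in AAD medium. Of the 11 genes named, Slc7a11 kept its call in all these runs, and the values of the others in runs that lost it are given in brackets. Nr4a1 lost it without WT replicate 2 (-0.99) or Cebpg-/- replicate 1 (-0.98) in normal medium, Ccl3 without WT replicate 3 in either medium or Cebpg-/- replicate 1 in normal medium (1.37 to 1.43), and Hivep3 without WT replicate 3 in normal medium (0.99) or Cebpg-/- replicate 2 in AAD medium (0.99). Clec4e lost it without WT replicate 2 or Cebpg-/- replicate 1 in normal medium, or WT replicate 3 or Cebpg-/- replicate 2 in AAD medium (1.59 to 1.67). Trib3 lost it without WT replicates 2 or 3 or Cebpg-/- replicates 1 or 3 in normal medium, or WT replicate 3 or Cebpg-/- replicate 2 in AAD medium (-1.42 to -1.57). Fgf21 lost it without WT replicates 2 or 3 or any Cebpg-/- array in normal medium, or Cebpg-/- replicates 1 or 2 in AAD medium (-1.51 to -1.69). Akr1c14 lost it without WT replicates 2 or 3 or Cebpg-/- replicates 1 or 2 in normal medium, or WT replicate 3 or Cebpg-/- replicate 2 in AAD medium (1.08 to 1.17). Of the WT and Cebpg-/- arrays, Il7r kept its call only without Cebpg-/- replicate 3 in normal medium (0.86 to 1.10 in the others), Sema7a only without replicate 1 of WT or replicate 3 of Cebpg-/- in AAD medium (1.25 to 1.45), and Inka1 only without WT replicate 1 in either medium (1.01 to 1.30). With the groups of this comparison alone Trib3 (adjusted p = 0.0707), Fgf21 (0.0926), Clec4e (0.0707), Il7r (0.0654) and Inka1 (0.147) also lost it. With the mean of their probe sets Sema7a (0.95, adjusted p = 0.0652) and Hivep3 (0.13, adjusted p = 0.884) lost it, Inka1 with no filter on dim probe sets (adjusted p = 0.0584), and Sema7a and Inka1 with a replicate block common to all groups (adjusted p = 0.0607 for each).

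Among the 248 AAD-induced genes, 12 had a smaller response in Cebpg-/-: Acot2 (-0.83 ± 0.15), Chd2 (-0.53 ± 0.09), Fgf21, Herpud1, Klf10 (-0.63 ± 0.11), Klf4 (-0.95 ± 0.14), Lrig3 (-0.78 ± 0.08), Sertad4 (-0.86 ± 0.12), Skil (-0.58 ± 0.09), Slc7a11, Spata1 (-0.73 ± 0.14) and Trib3. Spata1 lay under 4.65 in normal medium in WT (4.43 ± 0.12, SD, n = 3) and in Cebpg-/- (4.25 ± 0.18). Those outside the rule for named genes were chosen after their values were seen. All 12 also had a smaller response in Atf4-/-, against 10.4 for independent lists and 0 in the simulations. The interaction effects of the knockouts had a covariance of 0.028 over genes, against 0.008 in the simulations, and a correlation of 0.548 against 0.5, and genes are not independent replicates. The 12 became 44 with the replicate block, all 44 of them also smaller in Atf4-/-. They became 5 without WT replicates 2 or 3 in normal medium, WT replicate 3 or Cebpg-/- replicate 2 in AAD medium, 6 without Cebpg-/- replicates 1 or 3 in normal medium, 7 without Cebpg-/- replicate 2 in normal medium, and 21 without Cebpg-/- replicate 3 in AAD medium.

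**Figure D3:**
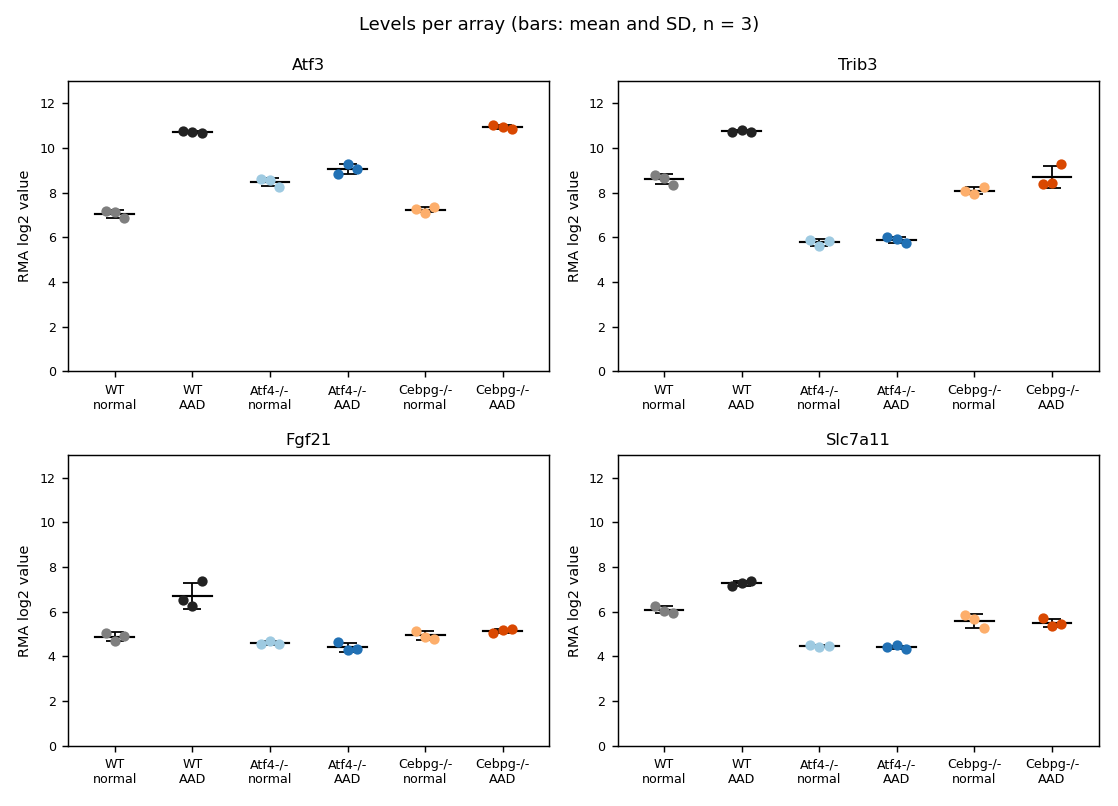
RMA log2 levels of Atf3, Trib3, Fgf21 and Slc7a11 on each of the 18 arrays (points), with the mean and SD of 3 arrays (bars). Atf3 rose by 3.67 in WT and 3.70 in Cebpg-/- but by 0.59 in Atf4-/-, while the responses of Trib3, Fgf21 and Slc7a11 were lower than in WT in both knockouts.

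The responses of the knockouts were also compared with each other. Those of Egr1 (3.53 ± 0.25), Atf3 (3.12 ± 0.17), the keratin-associated gene Krtap1-5 (2.99 ± 0.26) and Cxcl2 (2.42 ± 0.27) were higher in Cebpg-/- than in Atf4-/-. The sizes for Krtap1-5 and Cxcl2 are uncertain, since Krtap1-5 lay under 4.65 in Atf4-/- in both media (3.89 ± 0.22 and 3.60 ± 0.21, SD, n = 3) and in Cebpg-/- in normal medium (4.53 ± 0.37), and Cxcl2 in both knockouts in normal medium (4.29 ± 0.13 and 4.48 ± 0.17). Of the immediate early list, 22 of 34 members had a higher response, 1 had a lower response and 11 did not pass. Adjusted over the immediate early list alone 27 had a higher response and 1 had a lower response, at a median of 0.77 (camera adjusted p = 6.87e-29, adjusted p = 0.0337 with an estimated correlation). In the C/EBP and ATF family 4 of 23 members had a higher response and 19 did not pass, with Ddit3 at 1.37 ± 0.14. For the C/EBP and ATF list the median was 0.20 (camera adjusted p = 9.68e-06, adjusted p = 0.0431 with an estimated correlation), and 6 had a higher response adjusted over the list alone. Of the stress response regulators, 6 of 22 members had a higher response and 16 did not pass. For the stress response list the median was 0.37 (camera adjusted p = 6.46e-08, adjusted p = 0.0558 with an estimated correlation), and 7 had a higher response and 1 had a lower response adjusted over the list alone. Of the inflammatory mediators, 8 of 22 members had a higher response and 14 did not pass. The inflammatory median was 0.51 (camera adjusted p = 7.8e-09, adjusted p = 0.0558 with an estimated correlation), and 11 had a higher response adjusted over the list alone. Of the FOXO-type genes, 6 of 20 members had a higher response, 1 had a lower response and 13 did not pass. Adjusted over the FOXO-type list alone 9 had a higher response and 2 had a lower response, at a median of 0.37 (camera adjusted p = 2.28e-05, adjusted p = 0.26 with an estimated correlation). In the autophagy and lysosome list 7 of 31 members had a higher response and 24 did not pass. Adjusted over the autophagy and lysosome list alone 8 had a higher response, at a median of 0.07 (camera adjusted p = 0.00475, adjusted p = 0.608 with an estimated correlation). In the sterol synthesis list 1 of 20 members had a lower response and 19 did not pass. The sterol median was -0.22 (camera adjusted p = 0.000217, adjusted p = 0.388 with an estimated correlation), and 4 had a lower response adjusted over the list alone. As lists, the 19 synthetases were higher (median 0.09, camera adjusted p = 0.0358, 0.476 with an estimated correlation) and the 15 macrophage markers lower (median -0.21, camera adjusted p = 0.0435, 0.816 with an estimated correlation). In limma 0 members of either passed, and 5 synthetases and 2 macrophage markers had an unadjusted p under 0.05. Over all genes 507 responses were higher in Cebpg-/- and 221 lower, 728 in all, and 1824 differed with the replicate block. Array weights gave 1845, the C/EBP and ATF call was lost with the replicate block and an estimated correlation together (adjusted p = 0.112), and with the block alone the p53 targets (adjusted p = 0.036, against 0.0672) and smooth muscle markers (adjusted p = 0.0382, against 0.282) were called, though not with an estimated correlation as well (adjusted p = 0.345 and 0.271). The response of Atf4 itself passed only with the block (0.44 ± 0.13, adjusted p = 0.0721, or 0.00485 with the block).

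The next comparison asked how Atf4-/- cells differed from WT before deprivation. In normal medium they had far less Aldh1l2, a mitochondrial folate enzyme gene (-4.78 ± 0.12), Cth, which makes cysteine from cystathionine (-4.53 ± 0.16), Chac1, a glutathione-degrading enzyme gene (-4.04 ± 0.22), and the matrix proteoglycan gene Fmod (-5.00 ± 0.28). Of the amino acid synthesis genes, 18 of 23 members were lower, 2 were higher and 3 did not pass, including Psph (-3.07 ± 0.07). The amino acid synthesis median was -1.56 (camera adjusted p = 7.04e-10, adjusted p = 0.0337 with an estimated correlation), and 18 were lower and 2 were higher adjusted over the list alone. Of the aminoacyl-tRNA synthetases, 14 of 19 members were lower and 5 did not pass, with Cars at -2.23 ± 0.07. For the synthetase list the median was -0.71 (camera adjusted p = 1.15e-08, adjusted p = 0.0417 with an estimated correlation), and 15 were lower adjusted over the list alone. Sterol synthesis genes were lower throughout: 20 of 20 members were lower, with Idi1 at -2.88 ± 0.09 and Hmgcs1 at -2.25 ± 0.10. Adjusted over the sterol list alone 20 were lower, at a median of -1.31 (camera adjusted p = 6.52e-16, adjusted p = 0.0431 with an estimated correlation). Stress response regulators differed too: 13 of 22 members were lower, 5 were higher and 4 did not pass, with Nupr1 at -2.90 ± 0.29 and Trib3 at -2.82 ± 0.18. The stress response median was -0.87 (camera adjusted p = 0.00123, adjusted p = 0.26 with an estimated correlation), and 13 were lower and 5 were higher adjusted over the list alone. Of the amino acid transporters 12 of 22 members were lower, 4 were higher and 6 did not pass, with Slc7a3 at -3.54 ± 0.12. The transporter median was -0.25 (camera adjusted p = 0.00278, adjusted p = 0.134 with an estimated correlation), and 12 were lower and 4 were higher adjusted over the list alone. Sprr1a (4.10 ± 0.46) and Crct1 (4.02 ± 0.31) had the largest rises among genes with a proper name.

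Cell cycle genes were lower in Atf4-/- cells in normal medium: 27 of 28 members were lower and 1 did not pass, with Plk1, a mitotic kinase gene, at -2.73 ± 0.20 and Mki67 at -2.56 ± 0.25. The cell cycle median was -1.46 (camera adjusted p = 6.17e-12, adjusted p = 0.343 with an estimated correlation), and 27 were lower adjusted over the list alone. In the fibroblast matrix list 14 of 23 members were lower, 2 were higher and 7 did not pass, with S100a4 at -2.93 ± 0.14 and Col1a1, a collagen chain gene, at -1.97 ± 0.15. The fibroblast matrix median was -0.75 (camera adjusted p = 1.6e-05, adjusted p = 0.28 with an estimated correlation), and 14 were lower and 2 were higher adjusted over the list alone. In the endoplasmic reticulum list 12 of 22 members were lower, 2 were higher and 8 did not pass, with Herpud1 at -1.80 ± 0.07. The endoplasmic reticulum median was -0.24 (camera adjusted p = 0.000611, adjusted p = 0.576 with an estimated correlation), and 13 were lower and 2 were higher adjusted over the list alone. In the hypoxia and glycolysis list 12 of 20 members were lower, 7 were higher and 1 did not pass, with Ankrd37 (2.14 ± 0.22) and Adm (1.70 ± 0.23) higher and Vegfa (-1.25 ± 0.12) lower. Adjusted over the hypoxia and glycolysis list alone 12 were lower and 7 were higher, at a median of -0.34 (camera adjusted p = 0.0476, adjusted p = 0.614 with an estimated correlation). This call was lost with a replicate block common to all groups (adjusted p = 0.0502). Of the FOXO-type genes, 14 of 20 members were higher, 2 were lower and 4 did not pass. For the FOXO-type list the median was 0.48 (camera adjusted p = 0.00829, adjusted p = 0.572 with an estimated correlation), and 15 were higher and 2 were lower adjusted over the list alone. In the autophagy and lysosome list 20 of 31 members were higher, 3 were lower and 8 did not pass. For the autophagy and lysosome list the median was 0.31 (camera adjusted p = 0.00249, adjusted p = 0.576 with an estimated correlation), and 22 were higher and 3 were lower adjusted over the list alone.

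Over all genes, 4142 were higher and 2933 lower in Atf4-/- cells in normal medium, 7075 in all (51.5% of those tested), 487 and 538 of them by at least 2-fold. The sex-linked genes varied with the genotypes: all 6 WT arrays had Xist at or under 5.83 and Eif2s3y at or above 7.71, the pattern of male cells, all 6 Cebpg-/- arrays had Xist at or above 11.73 and Eif2s3y at or under 3.28, the pattern of female cells, and Atf4-/- replicate 1 was of the male and replicates 2 and 3 of the female pattern. Macrophage markers averaged 7.98 to 8.20 on WT arrays and 8.39 to 8.57 on Atf4-/- arrays in normal medium, where 8 of 15 members were higher, 1 was lower and 6 did not pass. The macrophage median was 0.34 (camera adjusted p = 0.168, adjusted p = 0.87 with an estimated correlation), and 8 were higher and 1 was lower adjusted over the list alone.

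Cebpg-/- cells were compared with WT in the same way. In normal medium Cebpg-/- cells had more Mmp13, a collagenase gene (4.24 ± 0.47), more Perp, a p53 target (3.05 ± 0.31), and more Nrcam, a neural cell adhesion gene (3.01 ± 0.08), and less Slc7a3, a cationic amino acid carrier gene (-3.44 ± 0.12), and Aspn, a matrix gene (-3.29 ± 0.39). The WT levels of Perp (4.38 ± 0.29, SD, n = 3) and Nrcam (3.40 ± 0.07) lay under 4.65, so the sizes of their differences are uncertain. Of the sterol synthesis genes, 18 of 20 members were lower and 2 did not pass, with Idi1 at -1.17 ± 0.09. For the sterol list the median was -0.73 (camera adjusted p = 3.27e-20, adjusted p = 0.0337 with an estimated correlation), and 19 were lower adjusted over the list alone. Of the NRF2-type oxidative stress genes, 12 of 19 members were higher, 2 were lower and 5 did not pass, with Hmox1, the heme oxygenase gene, at 2.01 ± 0.11, Nqo1 at 1.24 ± 0.14 and Gclm, which encodes a subunit of the glutathione-making enzyme, at 0.93 ± 0.09. The NRF2-type median was 0.42 (camera adjusted p = 9.83e-06, adjusted p = 0.0847 with an estimated correlation), and 13 were higher and 3 were lower adjusted over the list alone. In the fibroblast matrix list 12 of 23 members were lower, 1 was higher and 10 did not pass, with Thy1 (-1.53 ± 0.21) and Postn (-1.45 ± 0.22) lower and Mgp (2.06 ± 0.21) higher. Adjusted over the fibroblast matrix list alone 13 were lower and 1 was higher, at a median of -0.42 (camera adjusted p = 2.39e-08, adjusted p = 0.134 with an estimated correlation). Of the smooth muscle and myofibroblast markers, 10 of 14 members were lower and 4 did not pass, with Cnn1 at -1.01 ± 0.13. The smooth muscle median was -0.26 (camera adjusted p = 8.01e-07, adjusted p = 0.26 with an estimated correlation), and 10 were lower adjusted over the list alone. Among the amino acid synthesis genes 11 of 23 members were lower, 4 were higher and 8 did not pass, with Cth at -2.69 ± 0.16. Adjusted over the amino acid synthesis list alone 11 were lower and 4 were higher, at a median of -0.29 (camera adjusted p = 0.00109, adjusted p = 0.239 with an estimated correlation).

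Further shifts in Cebpg-/- cells concerned the synthetases, of which 7 of 19 members were lower and 12 did not pass. The synthetase median was -0.08 (camera adjusted p = 0.00441, adjusted p = 0.28 with an estimated correlation), and 8 were lower adjusted over the list alone. Of the transporters, 6 of 22 members were lower, 3 were higher and 13 did not pass. Adjusted over the transporter list alone 7 were lower and 3 were higher, at a median of -0.11 (camera adjusted p = 0.0156, adjusted p = 0.241 with an estimated correlation). Of the p53 targets, 11 of 21 members were higher and 10 did not pass. The p53 target median was 0.25 (camera adjusted p = 0.000554, adjusted p = 0.482 with an estimated correlation), and 13 were higher and 1 was lower adjusted over the list alone. Among C/EBP and ATF genes 6 of 23 members were lower, 1 was higher and 16 did not pass, with Creb3l1 at -1.25 ± 0.09. The C/EBP and ATF median was -0.07 (camera adjusted p = 0.0404, adjusted p = 0.324 with an estimated correlation), and 6 were lower and 1 was higher adjusted over the list alone. This list call was lost with a replicate block common to all groups (adjusted p = 0.0558). In the endoplasmic reticulum list 6 of 22 members were lower and 16 did not pass. Adjusted over the endoplasmic reticulum list alone 6 were lower, at a median of -0.06 (camera adjusted p = 0.00713, adjusted p = 0.694 with an estimated correlation). Macrophage markers averaged 8.73 to 9.14 on Cebpg-/- arrays in normal medium, above all WT arrays: 13 of 15 members were higher and 2 did not pass, with Lyz2 at 1.74 ± 0.18 and Cd68 at 1.28 ± 0.13. Adjusted over the macrophage list alone 13 were higher, at a median of 0.89 (camera adjusted p = 3.25e-09, adjusted p = 0.234 with an estimated correlation). Xist was higher by 6.04 ± 1.63 and the Y-linked genes Eif2s3y and Uty lower (-5.10 ± 1.34 and -4.04 ± 1.02), to levels under 4.65 (3.03 ± 0.10 and 3.17 ± 0.05, SD, n = 3), so these sizes are uncertain. Over all genes 1687 were higher and 1517 lower, 171 and 174 by at least 2-fold, and the total of 3204 became 2081 without Cebpg-/- replicate 3 in normal medium. The knockouts shared 1023 higher genes (509 for independent lists, 0 in the simulations) and 854 lower genes (324.1 and 0.02). The covariance of their differences from WT was 0.09, against 0.007 in the simulations, with a correlation of 0.441 against 0.497.

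**Figure D4:**
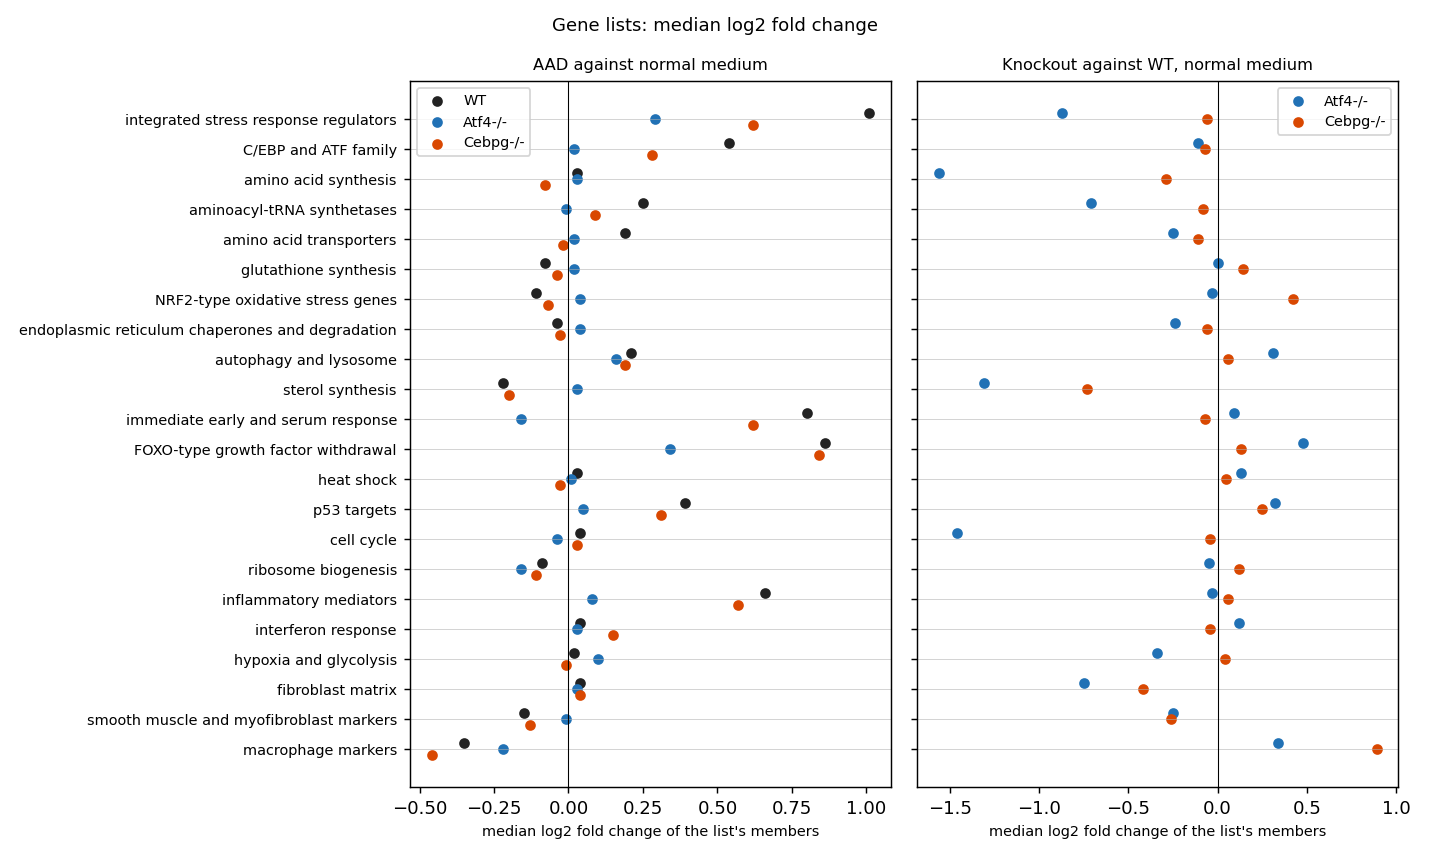
Median log2 fold change of 22 gene lists under AAD in each genotype (left) and in each knockout against WT in normal medium (right). Integrated stress response regulators had a median rise of 1.01 in WT, 0.29 in Atf4-/- and 0.62 in Cebpg-/-, and sterol synthesis genes had a median of -1.31 in Atf4-/- and -0.73 in Cebpg-/- in normal medium.

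The last comparisons took the levels in AAD medium. In Atf4-/- cells the chemokine gene Ccl2 was lower (-4.91 ± 0.21), as were Trib3 (-4.86 ± 0.18) and Cth (-4.96 ± 0.16). Stress response regulators were lower: 18 of 22 members were lower and 4 did not pass. Adjusted over the stress response list alone 18 were lower, at a median of -1.51 (camera adjusted p = 3.35e-11, adjusted p = 0.0337 with an estimated correlation). In the C/EBP and ATF family 14 of 23 members were lower, 4 were higher and 5 did not pass, with Atf5 at -2.91 ± 0.11. Adjusted over the C/EBP and ATF list alone 15 were lower and 4 were higher, at a median of -0.57 (camera adjusted p = 5.95e-06, adjusted p = 0.0431 with an estimated correlation). Of the synthetases, 16 of 19 members were lower and 3 did not pass. Adjusted over the synthetase list alone 16 were lower, at a median of -0.94 (camera adjusted p = 1.94e-09, adjusted p = 0.0337 with an estimated correlation). Of the inflammatory mediators, 16 of 22 members were lower, 1 was higher and 5 did not pass. Adjusted over the inflammatory list alone 16 were lower and 1 was higher, at a median of -0.70 (camera adjusted p = 2.33e-06, adjusted p = 0.11 with an estimated correlation). Of the immediate early genes, 26 of 34 members were lower, 2 were higher and 6 did not pass. For the immediate early list the median was -0.88 (camera adjusted p = 7.04e-10, adjusted p = 0.113 with an estimated correlation), and 27 were lower and 2 were higher adjusted over the list alone. Over all genes 4309 were higher and 3143 lower. Macrophage markers stood higher there: 12 of 15 members were higher, 1 was lower and 2 did not pass. For the macrophage list the median was 0.58 (camera adjusted p = 0.025, adjusted p = 0.794 with an estimated correlation), and 12 were higher and 1 was lower adjusted over the list alone.

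Cebpg-/- cells in AAD medium had lower levels of stress response and sterol genes than WT. Of the integrated stress response regulators, 12 of 22 members were lower and 10 did not pass, with Trib3 at -2.05 ± 0.18 and Fgf21 at -1.56 ± 0.20. For the stress response list the median was -0.51 (camera adjusted p = 9.28e-08, adjusted p = 0.0572 with an estimated correlation), and 14 were lower adjusted over the list alone. Of the amino acid transporters, 11 of 22 members were lower, 2 were higher and 9 did not pass, with Slc7a3 at -3.79 ± 0.12 and Slc7a11 at -1.76 ± 0.13. For the transporter list the median was -0.24 (camera adjusted p = 1.1e-05, adjusted p = 0.0431 with an estimated correlation), and 13 were lower and 2 were higher adjusted over the list alone. Among C/EBP and ATF genes 11 of 23 members were lower, 1 was higher and 11 did not pass. For the C/EBP and ATF list the median was -0.18 (camera adjusted p = 7.49e-05, adjusted p = 0.0572 with an estimated correlation), and 11 were lower and 2 were higher adjusted over the list alone. In the sterol synthesis list 19 of 20 members were lower and 1 did not pass. The sterol median was -0.66 (camera adjusted p = 8.4e-16, adjusted p = 0.0431 with an estimated correlation), and 19 were lower adjusted over the list alone. Of the NRF2-type genes 13 of 19 members were higher, 2 were lower and 4 did not pass. Adjusted over the NRF2-type list alone 14 were higher and 2 were lower, at a median of 0.53 (camera adjusted p = 1.44e-05, adjusted p = 0.089 with an estimated correlation). Of the macrophage markers 14 of 15 members were higher and 1 did not pass. The macrophage median was 0.74 (camera adjusted p = 6.55e-08, adjusted p = 0.279 with an estimated correlation), and 14 were higher adjusted over the list alone. Over all genes 2215 were higher and 1835 lower. Of the 248 AAD-induced genes, 101 were lower than WT in Cebpg-/- in AAD medium, 169 in Atf4-/- and 90 in both.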

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

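The tests of the macrophage share, of values near background, of less effective deprivation and of raised levels in normal medium were chosen after the results were seen, while those of sex, of flanking sequence and of other splits were set before. A test of the difference between genotypes singled out 10 results on the response to AAD. The response differed from WT for 1752 genes in Atf4-/- and for 31 in Cebpg-/-, and it differed between the knockouts for 728. Between Atf4-/- and WT the list tests differed for stress response regulators (adjusted p = 8.98e-13), the C/EBP and ATF family (6.61e-08) and immediate early genes (3.93e-22). Between Cebpg-/- and WT they differed for stress response regulators (1.48e-10) and amino acid transporters (1.24e-05). Between the knockouts they differed for the C/EBP and ATF family (9.68e-06) and immediate early genes (6.87e-29). With the replicate block and an estimated correlation together only the 2 immediate early calls were kept (adjusted p = 0.0255 for each). The others were lost (adjusted p = 0.104 to 0.293). Each of these comparisons allows 10 splits of its pairs of arrays, too few for a share under 0.05. The highest count of the splits other than the real one was 0 in each. The other splits mix genotypes that differ in level, which can widen the residual spread, so their low counts lend no support. The same holds for the AAD-induced genes with a smaller response in Atf4-/- (215), in Cebpg-/- (12) and in both (12), with 0 as the highest other. For the 6 arrays of each 2-group comparison, where other splits mix groups too, 1 of 10 gave as many genes, the real one. The real values and highest others were 3865 and 0 for AAD in WT, 645 and 141 in Atf4-/-, 3013 and 1 in Cebpg-/-, 7075 and 0 for Atf4-/- and 3204 and 0 for Cebpg-/- against WT in normal medium, and 7452 and 0 and 4050 and 0 in AAD medium. The splits with 141 genes and 1 gene parted 1 pair of arrays, and those that part 3 pairs, as the real one does, gave 0. At an unadjusted p under 0.05 in limma, the other splits gave 61 to 205, 125 to 262 and 78 to 153 different responses (real values 3456, 953 and 2423). They gave 208 to 961 genes for AAD in WT (real 5061), 217 to 2028 in Atf4-/- (2255) and 286 to 1596 in Cebpg-/- (4594). Against WT they gave 325 to 1053 (7742) and 250 to 1093 (4755) in normal medium and 245 to 818 (8071) and 338 to 1378 (5461) in AAD medium.

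In Atf4-/- cells 215 of the 248 AAD-induced genes had a smaller response. Less effective deprivation of these cultures as a uniform loss was argued against: 15 FOXO-type genes raised in WT kept 48.4 ± 1.8% of their response in Atf4-/-, and the 240 other AAD-induced genes 24.1 ± 0.8%, a difference of 24.3 ± 2 percent points (SE over 3 pairs of arrays). A raised level in normal medium as the whole cause was argued against for 157 of the 215 genes (73%), which were below WT in AAD medium. Of these, 75 were also above WT in normal medium, where a raised start may account for part of the smaller response. For the other 58 (27%), above WT in normal medium and not below it in AAD medium, a high starting level and a lost response cannot be told apart, since these levels define both groups. A need for ATF4 in part of the induction of the 157 genes is a candidate explanation. Less effective deprivation and other lasting differences of the Atf4-/- cells remain open.

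Ccl3 and Clec4e, with Cxcl2, Rgs1 and Cd83 named beside them, rose strongly under AAD in Cebpg-/-. The responses of Cxcl2 (1.30, adjusted p = 0.0566), Rgs1 (1.43, 0.0609) and Cd83 (1.12, 0.0801) did not pass against WT, except with the replicate block (0.0092, 0.0365 and 0.041). A larger share of macrophages may contribute: in AAD medium the 5 genes were above WT by 1.66 ± 0.19 and the 15 macrophage markers by 0.84 ± 0.13 (SE over 3 pairs of arrays), a gap of 0.82 ± 0.07, while the gap to Lyz2, the marker with the largest difference, was -0.09 ± 0.16, so the share cannot be told apart from a response of the cells. Values near background fit the test made for them on average: the 5 genes lay at -0.15 relative to the level of 4.65 in normal medium in WT, the lower of the genotypes. Clec4e and Cxcl2 lay under it in both genotypes. Rgs1 lay just 0.76 above it in WT and 0.60 in Cebpg-/-, and Cd83 0.41 and Ccl3 0.15 in Cebpg-/-. Background thus remains open for all 5. In normal medium the 5 genes differed by 0.24 ± 0.10 and the markers by 0.90 ± 0.14. Nothing in the labels describes a sort that would remove such cells.

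In normal medium 7075 genes differed between Atf4-/- and WT and 3204 between Cebpg-/- and WT. Sex as the whole cause in Atf4-/- was argued against, since the male pattern replicate showed a median of 0.92 of the difference of the female pattern replicates in AAD medium and 0.94 in normal medium, though this rests on 1 male replicate number. For Cebpg-/-, all of the female pattern against WT of the male pattern, the difference between female and male Atf4-/- replicates was a median of 0.03 of the Cebpg-/- difference at most, which also rests on 1 male replicate number. Few genes lie within 20 Mb of the loci. Their small share of calls (2.14% for Atf4-/-, 2.15% for Cebpg-/-) cannot test donor strain sequence. They were called less often than elsewhere (Fisher's exact test, odds ratio 0.69, p = 0.000983, and 0.67, p = 0.00231). Sex remains open for the genes that differ in Cebpg-/-. Lasting effects of the knockouts, donor sequence elsewhere and differences between embryos or cultures remain open and untested.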

How the results depend on the processing

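Settings with a replicate block within genotype or without both arrays of a replicate number were chosen after seeing the data, and the others were planned. No called result changed direction. The 3 arrays per group, or 2 with an array left out, limit precision. Of 127 results on named genes, 111 kept their call under all settings that scored them, which left out no pair of arrays. The planned log2(value + 16) was not run, since the deposited values were already log2. The cause of the moves below was not tested, except that fewer arrays or a stricter threshold lower a count by construction.

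Under the filter at the 60th percentile, 19 AAD-induced genes had a smaller response in Cebpg-/- and 19 in both knockouts. The mean of probe sets put the median response in Atf4-/- at 0.353. The trended and robust prior gave 56 different responses in Cebpg-/- and 21 and 21 AAD-induced genes. Array weights gave 2037 genes for AAD in Atf4-/-, 2857, 138 and 1845 different responses (Atf4-/-, Cebpg-/-, between the knockouts), 38 and 38 AAD-induced genes and a median of 0.331 in Atf4-/-. The groups of the comparison alone gave 329 genes for AAD in Atf4-/-. A further quantile normalization gave 55 different responses in Cebpg-/- and 22 and 22 AAD-induced genes. With a 2-fold minimum AAD changed 316, 32 and 219 genes (WT, Atf4-/-, Cebpg-/-), 212, 11 and 113 responses differed, and 1025 and 345 genes differed from WT in normal medium and 1074 and 364 in AAD medium. Without that minimum for AAD-induced genes the classes held 885, 19 and 19. The level in AAD medium in place of the response gave 101 and 90.

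The replicate block within genotype gave 1523 genes for AAD in Atf4-/- and 4663 in Cebpg-/-, 3270, 189 and 1824 different responses, and 44 and 44 AAD-induced genes, and as a random effect 1633, 4739, 3306, 221, 1912, 49 and 49. An estimated correlation left 20 list calls over the 10 comparisons. Over the 6 comparisons of responses, the replicate block with an estimated correlation gave 5, of which the 3 of the FOXO-type list were not called with an estimated correlation alone. The test fry, whose null is no change and not that of camera, did not call ribosome biogenesis (adjusted p = 0.0951) and macrophage markers (0.212) for AAD in Atf4-/-, p53 targets (0.0989) for the response in Atf4-/-, synthetases (0.0621), amino acid synthesis (0.197) and hypoxia and glycolysis (0.261) for that in Cebpg-/-, synthetases (0.0557), autophagy (0.0648) and macrophage markers (0.344) between the knockouts, and for Cebpg-/- against WT the endoplasmic reticulum list (0.0869) in normal medium and immediate early genes (0.0717) in AAD medium. Near the loci, the odds ratio was 0.85 for the whole chromosome of Atf4 and 0.71 within 10 Mb of Cebpg, neither past the threshold.

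Without both arrays of a WT replicate number (1, 2, 3), 8, 1 and 5 responses differed in Cebpg-/-, the classes for Cebpg-/- and for both held 4, 1 and 3, and without numbers 2 and 3 the different responses in Atf4-/- were 1155 and 1122. Without Atf4-/- numbers 1, 2 and 3, AAD in Atf4-/- changed 262, 201 and 358 genes, and without number 2 the different responses were 1030 against WT and 409 between the knockouts. Without Cebpg-/- numbers 1 and 2, AAD in Cebpg-/- changed 1963 and 1888 genes, 9 and 2 responses differed from WT, 482 and 440 between the knockouts, and the classes held 3 and 1.

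Leaving out 1 array gave 3170 to 3357 genes for AAD in WT, 334 to 641 in Atf4-/- and 2226 to 2652 in Cebpg-/-, 1346 to 1633, 8 to 51 and 500 to 753 different responses, and 6504 to 6658, 2081 to 3006, 6791 to 7035 and 2924 to 3824 genes for Atf4-/- and Cebpg-/- against WT in normal and then AAD medium. The classes held 208 to 223 in Atf4-/- and 5 to 21 in Cebpg-/- and in both. The medians were 1.309 to 1.355 in WT (lowest without WT replicate 1 in normal medium), 0.27 to 0.322 in Atf4-/- (highest without Atf4-/- replicate 3 in normal medium) and 1.119 to 1.205 in Cebpg-/-.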

Other observations

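Lists outside the comparisons above gave no call in any of the 10 comparisons at the preset correlation. Glutathione synthesis genes had their lowest adjusted p in Atf4-/- against WT in normal medium, with Cth at -4.53 ± 0.16, Chac1 at -4.04 ± 0.22 and Slc7a11 at -1.61 ± 0.13 (camera adjusted p = 0.161, 0.473 with an estimated correlation). The Atf4-/- level of Slc7a11 there (4.48 ± 0.05, SD, n = 3) lay under 4.65. The lowest adjusted p of the other lists were 0.081 for erythroid markers (Cebpg-/- against WT response), 0.105 for the interferon response (AAD in Cebpg-/-), 0.129 for endothelial markers (Atf4-/- against WT response), 0.168 for adipocyte markers (Cebpg-/- against WT in normal medium), 0.189 for sex-linked genes (the same), 0.198 for epithelial markers (Cebpg-/- against Atf4-/- response), 0.289 for heat shock genes (AAD in Atf4-/-), 0.428 for neural markers (Atf4-/- against WT in AAD medium) and 0.554 for skeletal muscle markers (Atf4-/- against WT in normal medium).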
